A study of Rattus norvegicus with 9 samples.

How the data were processed

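RNA sequencing was done on mesenteric and pulmonary arteries of adult rat offspring aged 3 to 5 months. Their dams drank ordinary water (control, CON) or 20% sucrose water (high sucrose, HS) during pregnancy. In all, 9 libraries of 3 groups were analysed, 3 per group: mesenteric artery of control offspring (replicates 1, 2 and 3), mesenteric artery of high-sucrose offspring (replicates 1, 2 and 3) and pulmonary artery of control offspring (replicates 1, 2 and 4). Pulmonary artery replicate 3 of the controls and pulmonary arteries of the high-sucrose group were not analysed here. Per the labels, messenger RNA was enriched with oligo(dT) beads, fragmented and copied with random primers, with a reagent that marks the second strand.

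The authors deposited 1 table of whole-number counts per gene for each library, with no normalization, and named the genome build rn7. The aligner, the counting program, the annotation and the strand counted are not given in the sources used here. Reads that gene copies, processed pseudogenes or antisense transcripts share with a named gene are therefore not separable. Each file held 30452 features, of which 7092 had an Ensembl identifier in place of a symbol. A total of 235 names stood on more than 1 line, 2394 lines in all, and every line was analysed as a feature of its own. No genome sequence was at hand, so no positions are given.

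Total counts per library ran from 10388231 to 15420546. The floor used for a gene with no counts in a group was 3 counts over that group, and genes with 1 to 3 counts were given a ratio with an exact conditional interval at 95% confidence. The reads carry no molecular identifiers, so floors and intervals cover counting error only.

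Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization factors, filterByExpr on the groups compared and robust estimation of the dispersion prior. Only the 6 libraries of a comparison entered its fit. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed at an adjusted p under 0.05. Levels of tested genes are CPM, the counts scaled to a common library size, on TMM-scaled totals, given as mean and SD over 3 libraries. Levels of cell type markers in single libraries and the plots of markers and Hox genes use CPM on totals scaled by TMM over all 9 libraries. Standard errors of log2 fold changes are the fold change divided by the square root of F.

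A total of 47 gene lists with 926 distinct genes covered artery function, metabolism, stress responses, developmental transcription factors and markers of other cell types. Of these genes, 853 were found by symbol, 2 of them by an older name. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01 and 2-sided p-values adjusted over the lists. The list of sex-linked genes served only as a check of the animals and was not tested. For each list, p-values of its members were also adjusted over the list alone. Values of 1 list and of some single genes are not reported here.

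The comparisons, the tests, the lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule names up to 8 genes with the largest rise and 8 with the largest fall among those that passed. It also asks for a mean log2 CPM of at least 1, a symbol and no overlap between groups. The mean log2 CPM was taken as the average log2 CPM that edgeR computes. By a plain mean of log2 CPM over the libraries, Nkx2-3 (0.60) and Hoxc8 (−0.84) would lie below 1 between pulmonary and mesenteric artery. It adds up to 3 members with the smallest p from each list that had a call, and 8 cell type markers. Where fewer than 10 genes pass, it also names the 10 genes with the smallest p that meet the level and symbol criteria.

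The alternative settings fixed then were size factors by median ratio, upper quartile factors, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a stricter filter (10 counts in every library of a group and a mean of 1 CPM), all 9 libraries in 1 fit, the replicate number as a block, each library left out in turn, a correlation between list genes estimated from the data, and fry. After the data were seen, 3 more were added: the newer quasi-likelihood method of edgeR, the contractile score (mean log2 CPM of the contractile list) as a covariate, and pulmonary artery replicate 1 as the only pulmonary library.

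Nothing in the labels says that the samples of a group came from separate animals or litters, so the p-values measure the spread between samples, which may be technical. Between libraries of a group, chi-square per degree of freedom was 42.5 to 312, where counting error alone gives about 1. These values argue against repeat sequencing of the same library, but they do not show separate animals. The test was tried on simulated changes in 200 genes of each comparison, in 5 draws. Of genes changed 2-fold, 4-fold and 8-fold, it recovered 8.33%, 64.5% and 90.6% with the spread of the mesenteric comparison, with 52 false among 611 calls. With the spread of the artery comparison it recovered 0.314%, 10.9% and 55.8%, with 20 false among 249 calls. Lists of 20 genes moved 2-fold were found in 5 of 5 draws in each comparison, and lists of 20 random genes in 0 of 5, at an unadjusted p under 0.05. The simulated genes varied independently of each other. These draws therefore cannot show how often a list of correlated genes is called falsely.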

Results

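Gene expression was measured by sequencing of poly(A) RNA from arteries of adult rats whose dams drank ordinary water or 20% sucrose water in pregnancy. Mesenteric artery of control offspring, mesenteric artery of high-sucrose offspring and pulmonary artery of control offspring were represented by 3 libraries each. Total counts were 14910903, 11011268 and 11135307 in mesenteric control replicates 1, 2 and 3. They were 12357489, 10388231 and 11272367 in mesenteric high-sucrose replicates 1, 2 and 3, and 11194622, 15420546 and 15121677 in pulmonary control replicates 1, 2 and 4. The share of counts from the mitochondrial genome was 12.8% to 16.7% in the mesenteric controls, 13.8% to 20.0% in the mesenteric high-sucrose libraries and 13.9%, 20.1% and 27.1% in pulmonary replicates 1, 2 and 4.

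Every library held the smooth muscle genes Acta2 and Myh11 and the endothelial gene Pecam1, and all 9 held the Y-linked genes Kdm5d and Eif2s3y. Acta2, the smooth muscle actin, ran from 1025 to 8244 CPM within the mesenteric controls, lowest in replicate 2, and was 748 CPM in pulmonary replicate 4 against 6084 and 6792 CPM in pulmonary replicates 1 and 2. Pulmonary replicate 4 was the highest of the 9 libraries for 22 of 22 lymphocyte markers and 13 of 13 lung epithelium markers, with Cd3e, a part of the T cell receptor complex, at 86.6 CPM and Scgb1a1, a club cell secretoglobin, at 388 CPM. In pulmonary replicate 1 these genes were at 3.89 and 0.17 CPM. Pulmonary replicate 2 was the highest for 18 of 18 cardiac muscle markers, with Myh6, the atrial myosin heavy chain, at 6074 CPM against 465 CPM in replicate 4 and 2.65 CPM in replicate 1. Sftpc, the alveolar surfactant protein, was at 0.08, 28.2 and 62.2 CPM in pulmonary replicates 1, 2 and 4, and Ucp1, the uncoupling protein of brown fat, at 12.6, 4.08 and 0.45 CPM. In the 6 mesenteric libraries Sftpc stayed at or below 0.54 CPM and Ucp1 at or below 0.19 CPM. Adipoq, an adipocyte hormone, was at 203, 152 and 6.58 CPM in pulmonary replicates 1, 2 and 4 and between 109 and 262 CPM in the mesenteric libraries.

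**Figure D1:**
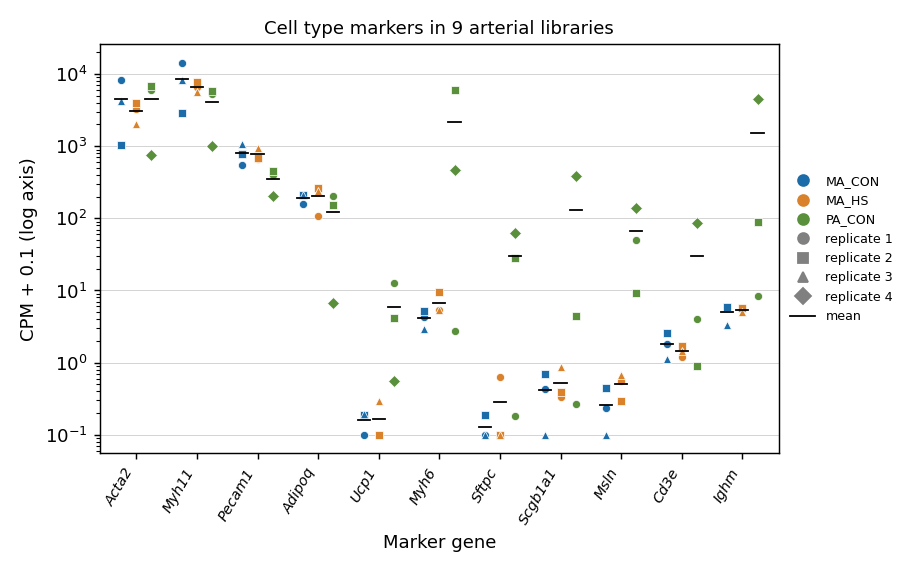
CPM plus 0.1 (log axis) of 11 cell type marker genes in the 9 libraries, with colour for the group, symbol for the replicate and a bar for the group mean. Pulmonary replicate 4 has the highest Scgb1a1 (388 CPM) and Cd3e (86.6 CPM), and pulmonary replicate 2 the highest Myh6 (6074 CPM).

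The first comparison asked which genes differed in the mesenteric artery between offspring of sucrose-drinking dams and control offspring. Heat shock proteins, which fold or hold other proteins, were higher as a list in the high-sucrose group (10 of 10 tested members, median log2 fold change 0.75), but not in all 3 libraries. The mean of the list was 9.39 log2 CPM in each of replicates 1 and 3 and 7.72 log2 CPM in replicate 2, below the controls (8.37, 8.48 and 7.73 log2 CPM). Genes of the circadian clock were also higher as a list, with Per2, a repressor of the clock, at 185 ± 89.8 CPM against 63.0 ± 16.0 CPM in control (SD, n = 3 per group). Of 17 tested clock genes, 11 were higher and 6 lower, with Arntl among the lower (log2 fold change −1.02). Interferon response genes, markers of adventitial fibroblasts and lymphocytes, nuclear genes of the respiratory chain and ribosomal proteins were lower as lists. No single gene passed the test over all genes, and each list call was lost when the correlation between genes was estimated (adjusted p = 0.709 with an estimated correlation).

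Of 13995 genes tested with edgeR, 0 passed, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 there were 279 genes (1.99%), and the groups did not overlap for 853 genes (6.10%, where chance gives 10%). DESeq2 called 3 genes and limma-voom with quality weights called 0. The 3 genes called by DESeq2 were Cryab, a small heat shock protein of muscle, Hspe1, the co-chaperonin of mitochondria, and Apcdd1l. Cryab was at 328 ± 31.9 CPM in control and 838 ± 224 CPM in the high-sucrose group, a log2 fold change of 1.35 ± 0.26 (SE), with an adjusted p of 0.0270 by DESeq2. Hspe1 was at 92.0 ± 5.80 and 212 ± 52.4 CPM, a log2 fold change of 1.20 ± 0.22, and Apcdd1l at 24.8 ± 2.46 and 9.71 ± 2.29 CPM, a log2 fold change of −1.35 ± 0.23, both with an adjusted p of 0.0290 by DESeq2. Over all alternatives the adjusted p of these 3 genes ran from 0.0270 to 1.00.

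The other genes with the smallest p, none past the threshold, did not overlap between the groups, which a choice by smallest p makes likely. Lower in all 3 high-sucrose libraries were Crot, the peroxisomal carnitine octanoyltransferase (log2 fold change −0.73), Thy1, a surface protein of fibroblasts and neurons (−1.11), Islr (−0.79) and Sema3c, a secreted semaphorin (−0.83). Higher in all 3 were Sdk2, a cell adhesion protein (1.09), Itprip, a partner of the inositol trisphosphate receptor (1.03), and Rbp7, a retinoid binding protein (1.74, from 7.48 ± 2.81 to 25.0 ± 11.3 CPM).

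**Figure D2:**
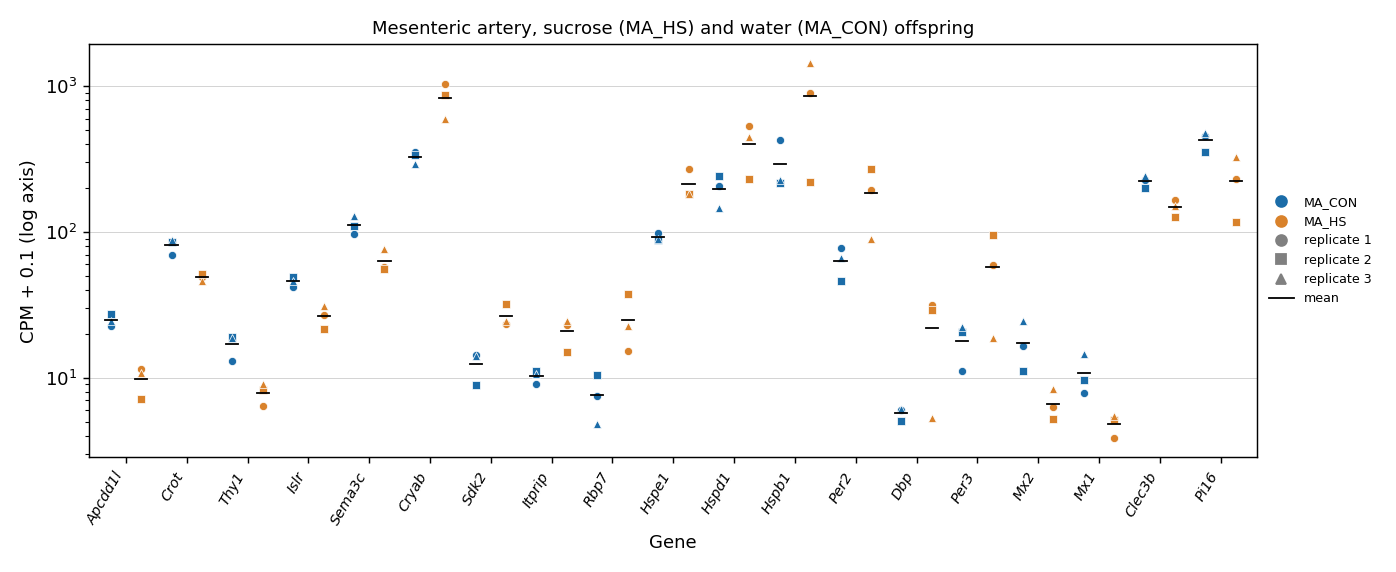
CPM plus 0.1 (log axis) of 19 genes in the 6 mesenteric libraries, with colour for the group, symbol for the replicate and a bar for the group mean. Cryab lies near 838 CPM in the high-sucrose group and near 328 CPM in control, whereas Hspb1 and Hspd1 of high-sucrose replicate 2 lie within the control range.

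Of 42 lists tested, 10 passed, 5 higher and 5 lower in the high-sucrose group. With an estimated correlation 0 passed, 1 list was at an unadjusted p under 0.05, and each of the 10 had an adjusted p = 0.709 with an estimated correlation. Fry called 0 lists, with 0 at an unadjusted p under 0.05 and an adjusted p = 0.815 for each of the 10. Over all alternatives the adjusted p of the 10 lists ran from 2.8e-23 to 0.815.

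The heat shock list (10 genes, adjusted p = 3.2e-06) had 1 member past the threshold when adjusted over the list alone, Hspe1. Its partner Hspd1, the mitochondrial chaperonin, had a log2 fold change of 1.02 ± 0.35 and Hspb1, a small heat shock protein, 1.55 ± 0.65 (SE, 0.93 without high-sucrose replicate 3). Both overlapped control in high-sucrose replicate 2, where Hspb1 was at 219 CPM against 897 and 1443 CPM in replicates 1 and 3. The list of the unfolded protein response, the stress response of the endoplasmic reticulum, had 17 of 18 genes higher (median 0.37, adjusted p = 1.3e-04), with Asns at 1.06 (1.62 without control replicate 2), Atf6 at 0.48 and Dnajb9 at 0.58, and 0 genes adjusted over the list alone. Without high-sucrose replicate 3 its median was 0.05, Dnajb9 was at −0.080 and the call ended.

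The clock list had 11 of 17 genes higher (median 0.46, adjusted p = 6.9e-05), with log2 fold changes of 1.55 for Per2, 1.96 for Dbp and 1.70 for Per3, and 0 genes adjusted over the list alone. The 6 lower members included Arntl at −1.02, Npas2 at −0.84 and Clock at −0.27. Arntl was at 65.9 ± 1.28 CPM in control and 32.5 ± 29.4 CPM in the high-sucrose group. Dbp, a transcription factor driven by the clock, was at 31.4 and 28.9 CPM in high-sucrose replicates 1 and 2 and at 5.22 CPM in replicate 3, within the control range of 4.91 to 6.03 CPM. The call ended without control replicate 2 (median 0.22), and the median was 0.82 without control replicate 3.

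Adipocyte markers had 15 of 17 genes higher (median 0.54, adjusted p = 5.0e-06, 0 adjusted over the list alone). Cidec, a lipid droplet protein, was at 1.18 (0.74 without high-sucrose replicate 2), Pck1, which makes glycerol for triglycerides in fat, at 0.93 and Pnpla2, a triglyceride lipase, at 0.72, while Adipoq was at 0.09. The median was 0.12, and the call ended, without high-sucrose replicate 2, and it was 0.88 without high-sucrose replicate 1. Cell cycle genes had 14 of 17 higher (median 0.42, adjusted p = 0.0074, 0 adjusted over the list alone), with Tpx2 at 0.68, Ube2c at 1.36 (0.63 without high-sucrose replicate 3, 2.28 without control replicate 3) and Mcm6 at 0.40 (0.18 without high-sucrose replicate 3). Their call ended without control replicate 1 (0.27) or 2 (0.53), the median turned to −0.21 without high-sucrose replicate 3, and it was 0.82 without control replicate 3 and 0.83 without high-sucrose replicate 1.

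Interferon response genes had 11 of 15 lower (median −0.44, adjusted p = 1.9e-05, 0 adjusted over the list alone). The mean of the list was 3.84, 3.88 and 4.46 log2 CPM in high-sucrose replicates 1, 2 and 3. Replicate 3 thus lay within the controls (4.18, 4.51 and 4.70 log2 CPM). The antiviral GTPases Mx2 and Mx1 had log2 fold changes of −1.41 ± 0.35 and −1.18 ± 0.33 (SE), from 17.3 ± 6.72 to 6.50 ± 1.59 CPM and from 10.6 ± 3.54 to 4.68 ± 0.83 CPM. Bst2, another antiviral gene of the list, was at 0.77. T and B lymphocyte markers had 10 of 11 lower (median −0.66, adjusted p = 0.0011, 0 adjusted over the list alone), all at low counts, with Cd2 at −1.68, Cd79a at −0.77 (0.060 without control replicate 3), Cd3g at −0.72 (−0.31 and −1.32 without high-sucrose replicates 1 and 3) and Cd3e at −0.37 (−0.0048 and −0.63 without control replicates 2 and 3, −0.22 without high-sucrose replicate 1). Their call ended without control replicate 2 (−0.37) or high-sucrose replicate 1 (−0.22), and the median was −0.30 without control replicate 3.

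Fibroblast markers had 14 of 17 lower (median −0.30, adjusted p = 1.9e-04, 0 adjusted over the list alone), with Clec3b at −0.60, Pi16 at −0.93 (−0.61 without high-sucrose replicate 2) and Mfap5 at −0.70 (−0.37 without control replicate 2). That call ended without control replicate 2 (−0.16) or high-sucrose replicate 2 (−0.21), and the median was −0.46 without high-sucrose replicate 3. Nuclear respiratory chain genes had 28 of 30 lower (median −0.19, adjusted p = 1.9e-04, 0 adjusted over the list alone), with Cox5b at −0.40 (−0.22 without control replicate 3), Ndufa2 at −0.42 (−0.28 without control replicate 1) and Ndufa9 at −0.32. Without control replicate 3 the call ended (−0.11), and the median was −0.36 without control replicate 2 and −0.33 without high-sucrose replicate 3. Ribosomal protein genes had 26 of 27 lower (median −0.18, adjusted p = 0.0018, 0 adjusted over the list alone), with Rps23 at −0.45, Rps28 at −0.44 and Rps9 at −0.27, and the call ended without control replicate 2 (−0.10) or high-sucrose replicate 2 (−0.12).

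Lists of artery function did not pass. The contractile list had a median of −0.08 (adjusted p = 0.808), potassium channels 0.16 (0.227), calcium handling 0.09 (0.314), vasoconstrictor receptors −0.16 (0.721), dilator pathways −0.22 (0.499) and extracellular matrix −0.02 (0.483). Acta2 had a log2 fold change of −0.51, Myh11 of −0.33, Pecam1 of −0.05 and Myh6 of 0.71 (0.39 without high-sucrose replicate 2). Without control replicate 1, Acta2 was at 0.26 and Myh11 at 0.26, and without control replicate 2 at −0.98 and −0.74, while Pecam1 ran from −0.27 to 0.20 with 1 library left out. Among metabolic and stress lists, lipid metabolism had an adjusted p of 0.0505, mitochondrially encoded genes 0.0505, redox genes 0.0628, sugar uptake and glycolysis 0.370, glucocorticoid response 0.469, hypoxia response 0.596, and insulin signalling and inflammation 0.779 each. Immediate early genes had 0.808, Notch signalling 0.0628, epigenetic enzymes 0.227, BMP and TGF-beta signalling 0.295, thoracic transcription factors 0.731, Hox genes 0.736 and Wnt signalling 0.898. Among cell type markers, lymphatic endothelium had 0.0505, brown fat, mast cells and granulocytes, and blood endothelium 0.177 each, nerve 0.227, cardiac muscle 0.286, pericytes 0.352, skeletal muscle and cartilage 0.417 each, and macrophages 0.881. Mesothelium, gut, lung epithelium and red cell lists had too few tested genes in this comparison.

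The second comparison set pulmonary against mesenteric artery of control offspring. Nkx2-3, a homeobox transcription factor of the visceral mesoderm that forms gut and spleen stroma, fell from 48.3 ± 11.7 CPM in mesenteric to 0.069 ± 0.071 CPM in pulmonary artery (SD, n = 3 per group). Spon2, a secreted matrix protein, fell from 82.9 ± 20.0 to 4.54 ± 0.36 CPM. The Hox list fell, with its tested members of paralogous groups 5 to 9 lower in all 3 pulmonary libraries while none of groups 2 and 3 passed when adjusted over the list alone. Immediate early genes and endothelial markers were lower as lists in pulmonary artery, and mesothelium markers higher. Cardiac muscle markers were also higher as a list, but pulmonary replicate 2 was the highest library for 18 of 18 of them. With pulmonary replicate 1 as the only pulmonary library the cardiac median was 0.21. Each of these list calls was lost when the correlation between genes was estimated (adjusted p = 0.183 to 0.617 with an estimated correlation).

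Of 14315 genes tested, 2 passed, Nkx2-3 and Spon2, both lower in pulmonary artery. At an unadjusted p under 0.05 there were 1221 genes (8.53%), and the groups did not overlap for 2015 genes (14.1%, where chance gives 10%). Nkx2-3 had 1782 counts over the mesenteric and 3 over the pulmonary libraries, a ratio of 660 with a counting interval of 226 to 3205, and Spon2 a log2 fold change of −4.19 ± 0.28 (SE). Both had an adjusted p of 0.0226. DESeq2 called 462 genes and limma-voom with quality weights 33. Pulmonary replicate 4 was the highest library for the lymphocyte and lung epithelium markers. Pulmonary replicate 2 also held the lung epithelium transcript Sftpc (28.2 CPM against 62.2 CPM in replicate 4). Without replicate 4, but with replicate 2 in the fit, edgeR called 22 genes, 8 higher and 14 lower, Nkx2-3 and Spon2 among them. With mesenteric replicate 1, 2 or 3 or pulmonary replicate 1 or 2 left out, or with pulmonary replicate 1 as the only pulmonary library, it called 0, with an adjusted p from 0.105 to 0.243 for Nkx2-3 and from 0.128 to 0.196 for Spon2, whose log2 fold change then ran from −4.34 to −3.99.

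The other genes with the smallest p missed the threshold. Npy1r, a receptor of the vasoconstrictor neuropeptide Y, was at 170 ± 40.2 CPM in mesenteric and 9.83 ± 3.14 CPM in pulmonary artery (log2 fold change −4.11 ± 0.36 SE, adjusted p = 0.0546). Apcdd1l was at 25.0 ± 2.58 and 0.77 ± 0.49 CPM (−5.03), the olfactory receptor gene Olr59 at 138 ± 12.4 and 8.27 ± 4.36 CPM (−4.06), Itm2a at 122 ± 41.4 and 17.6 ± 1.87 CPM (−2.79) and Cxcl14, a chemokine, at 40.1 ± 13.5 and 3.30 ± 1.11 CPM (−3.60). Hoxb7, Hoxc8 and Hoxd8 completed the 10. Apcdd1l was thus among the genes with the smallest p of both comparisons, which share the mesenteric controls.

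Of 44 lists tested, 22 passed, 9 higher and 13 lower in pulmonary artery. With an estimated correlation 0 passed and fry called 0, each with 4 lists at an unadjusted p under 0.05. Over all alternatives the adjusted p of the 22 lists ran from 2.3e-36 to 0.809. With genes near 0 counts set at their bound, the medians were −3.24 for the Hox, 7.88 for the cardiac, 0.69 for the gut and 3.46 for the mesothelium list. These genes stayed on their side of the median, so this setting could not move it. Without pulmonary replicate 4, 8 of the 22 remained, those of Hox, immediate early, inflammation, cardiac, cartilage, endothelial, gut and mesothelium genes. With pulmonary replicate 1 as the only pulmonary library, 10 of the 22 passed, but the spread then came from the mesenteric libraries alone, and the lone library was assumed to vary like them.

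Hox genes, the transcription factors that set position along the body axis, had 19 of 21 tested members lower (median −3.24, adjusted p = 6.7e-32). The list had an adjusted p = 0.183 with an estimated correlation, and over its alternatives the adjusted p ran from 2.3e-36 to 0.183. Adjusted over the list alone, 14 fell and 0 rose: every tested member of paralogous groups 5 to 9, and Hoxc4 and Hoxd4. Hoxb7 was at 18.4 ± 5.24 CPM in mesenteric and 0.76 ± 0.23 CPM in pulmonary artery (log2 fold change −4.59) and Hoxd8 at 20.9 ± 5.20 and 2.20 ± 0.54 CPM (−3.24). Hoxc8 had 581 counts over the mesenteric and 1 over the pulmonary libraries, a ratio of 646 with a counting interval of 115 to 25553. Members that did not pass included Hoxa2 (−0.43), Hoxa3 (−0.21), Hoxa4 (0.70), Hoxb3 (−0.10), Hoxb4 (0.15) and Hoxd3 (−0.61). Without pulmonary replicate 4, where Hoxb3 was at 8.58 CPM against 53.7 and 49.9 CPM in replicates 1 and 2, these were at −0.033, 0.15, 1.04, 0.38, 0.59 and −0.031. Of 23 members tested there, 16 were lower, Hoxa9 and Hoxc9 added, and 2 higher, Hoxa4 and Hoxb4 (adjusted p = 0.0324 and 0.0376 over the list alone). Hoxa2 and Hoxa3 were at 0.17 and 0.31 without mesenteric replicate 3, Hoxd3 at 1.08 without mesenteric replicate 2, and Hoxb4 at −0.23 and −0.022 without pulmonary replicates 1 and 2. No change of scaling moved the median over all genes by more than 0.0143.

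**Figure D3:**
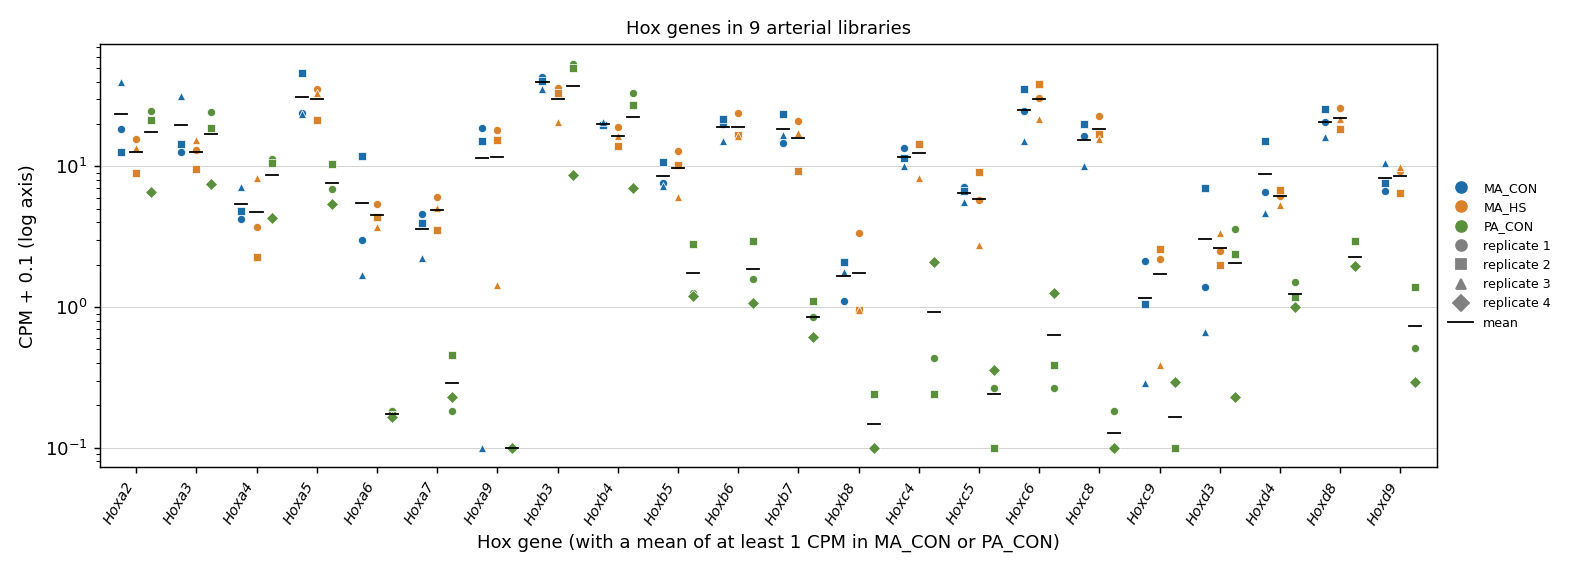
CPM plus 0.1 (log axis) of 22 Hox genes in the 9 libraries, with colour for the group, symbol for the replicate and a bar for the group mean. Hoxb7 lies between 14.5 and 23.6 CPM in the mesenteric controls and at or below 1.00 CPM in the pulmonary libraries, whereas Hoxa3 and Hoxb3 overlap between arteries.

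Immediate early genes, which respond to stimuli and to tissue handling within minutes, had 20 of 20 lower in pulmonary artery (median −2.02, adjusted p = 5.4e-18, 11 adjusted over the list alone). The list had an adjusted p = 0.443 with an estimated correlation, and its median was −1.32 without mesenteric replicate 3. Atf3 was at −2.46, Egr2 at −3.38 and Ier3 at −2.44. The inflammation list was lower (median −0.44, adjusted p = 0.0046, 1 adjusted over the list alone), with Il6 at −7.87, Cxcl1 at −5.62 and the B cell chemokine Cxcl13 at 6.80 (2.92 without pulmonary replicate 4). Its call ended without mesenteric replicate 2 (−0.28) or pulmonary replicate 1 (−0.54) or 2 (−0.64), and its median was −0.93 without mesenteric replicate 1 and −1.02 without pulmonary replicate 4. Glucocorticoid response genes were lower (median −0.30, adjusted p = 0.0245, 0 adjusted over the list alone), with the metallothioneins Mt2A and Mt1 at −2.87 and −2.70 and Hsd11b1, which regenerates glucocorticoids, at −1.39. That call ended without mesenteric replicate 2 (−0.36) or pulmonary replicate 4 (−0.02), and the median was −0.51, −0.58 and −0.65 without mesenteric replicate 1, pulmonary replicate 1 and pulmonary replicate 2. Both lists had an adjusted p = 0.674 with an estimated correlation.

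Among lists of the vessel wall, endothelial markers had 14 of 15 lower (median −0.89, adjusted p = 1.9e-06, 3 adjusted over the list alone), with an adjusted p = 0.617 with an estimated correlation and a median of −1.41 without pulmonary replicate 2. Erg, an endothelial transcription factor, was at 91.8 ± 8.04 CPM in mesenteric and 34.8 ± 10.4 CPM in pulmonary artery (−1.40 ± 0.28 SE), Esam at −1.79, Egfl7 at −1.83 (−1.12 without mesenteric replicate 2) and Pecam1 at −1.19. The contractile list had 16 of 20 lower (median −0.81, adjusted p = 1.3e-05, 0 adjusted over the list alone), with Actg2 at −1.72, Myl9 at −1.93 and Des at −1.94, while Myh11 was at −1.06 (−0.48 without mesenteric replicate 1, −0.60 without pulmonary replicate 4) and Acta2 at 0.02 (0.78 and −0.45 without mesenteric replicates 1 and 2). It had an adjusted p = 0.674 with an estimated correlation, and its median was −0.36 and no longer passed without pulmonary replicate 4, and −1.24 without pulmonary replicate 2. Extracellular matrix genes had 25 of 31 lower (median −0.51, adjusted p = 3.5e-05, 0 adjusted over the list alone), with Thbs1 at −3.89 and Timp1 at −1.67 (−2.43 and −0.96 without mesenteric replicate 2) and Col8a1 at −1.85. Their adjusted p = 0.674 with an estimated correlation, and without pulmonary replicate 4 the call ended (−0.14).

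Vasoconstrictor receptors and their ligands had 16 of 23 lower (median −0.43, adjusted p = 1.3e-04), with Npy1r and 1 other, Avpr1a, the vasopressin receptor (−3.04), past the threshold when adjusted over the list alone, and Edn1, endothelin, at −2.95. The list had an adjusted p = 0.617 with an estimated correlation, its call ended without pulmonary replicate 4 (−0.29), and its median was −0.71 without pulmonary replicate 2. Dilator pathways passed as lower (median −0.60, mean −0.28, adjusted p = 0.0335, 2 adjusted over the list alone), but with 10 of 18 genes lower and 8 higher. Calcrl, a receptor of the dilator peptides CGRP and adrenomedullin, was at −2.75, Cyp2j4 at −1.57 and Ptgir, the prostacyclin receptor, at −1.53. The dilator call ended without mesenteric replicate 2 (−0.06) or 3 (−0.33) or pulmonary replicate 4 (−0.16). BMP and TGF-beta signalling was lower (median −0.56, adjusted p = 0.0024, 2 adjusted over the list alone), with Grem1, a BMP antagonist, at −5.31, Bmp5 at −4.01 and Bmp2 at −1.94, and the call ended without pulmonary replicate 4 (−0.07), with a median of −0.36 without mesenteric replicate 3. Both lists had an adjusted p = 0.674 with an estimated correlation.

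Adventitial, nerve and lymphatic markers were lower as lists, each with an adjusted p = 0.674 with an estimated correlation. Fibroblast markers had a median of −0.55 (adjusted p = 0.0059, 0 adjusted over the list alone), with Dpt at −1.51, Igfbp6 at −1.41 and Fap at 2.23. The call ended without mesenteric replicate 2 (−0.22) or pulmonary replicate 4 (−0.27), and the median was −0.83 without pulmonary replicate 1. Nerve markers had a median of −0.74 (adjusted p = 0.0093, 2 adjusted over the list alone), with Cdh19, a gene of glial cells, at −2.49. Their call ended without mesenteric replicate 1 (−0.37), 2 (−0.18) or 3 (−0.39) or pulmonary replicate 1 (−0.39) or 4 (−0.53). Lymphatic markers had a median of −1.14 (adjusted p = 0.0106, 1 adjusted over the list alone), with Reln at −2.53, Mmrn1 at −3.58 (−2.03 without mesenteric replicate 2) and Sema3d at 3.25, and the call ended without mesenteric replicate 2 (−0.50) or pulmonary replicate 4 (−0.82).

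Higher in pulmonary artery were lists of other tissues, carried by different libraries. Cardiac muscle markers had 10 of 10 higher (median 7.88, adjusted p = 2.1e-08, 8 adjusted over the list alone), with Actc1, the cardiac actin, at 11.91 (mesenteric counts in replicate 1 only), the atrial myosin light chain Myl4 at 8.49 and Myh6 at 9.04 (5.86 without pulmonary replicate 2). Myl7, another atrial light chain, had 3 mesenteric and 38147 pulmonary counts, a mesenteric over pulmonary ratio of 8.7e-05 with a counting interval of 1.8e-05 to 2.6e-04. It varied widely between the pulmonary libraries (890 ± 1230 CPM, SD, n = 3). Its log2 fold change of 13.26 ran from 10.99 to 14.19 with 1 library left out and was 3.86 in the lowest alternative. The list had an adjusted p = 0.617 with an estimated correlation, and its median was 4.49 without pulmonary replicate 2 and 0.21 with pulmonary replicate 1 as the only pulmonary library. Mesothelium markers had 6 of 8 higher (median 3.46, adjusted p = 6.7e-08, 4 adjusted over the list alone), with an adjusted p = 0.374 with an estimated correlation and a median of 5.24 without mesenteric replicate 3. Msln was at 50.7, 9.17 and 137 CPM in pulmonary replicates 1, 2 and 4 and at most 0.57 CPM in the mesenteric libraries. Upk3b had 0 mesenteric and 310 pulmonary counts and was at least 93.0-fold higher, with the floor of 3 counts over the group, and Lrrn4 had 1 and 242 counts, a mesenteric over pulmonary ratio of 0.00459 with a counting interval of 0.000116 to 0.0258.

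Lymphocyte markers had 16 of 16 higher (median 4.33, adjusted p = 2.7e-06, 1 adjusted over the list alone), with Blk at 6.53, Jchain at 7.59, Mzb1 at 7.55 and Cd3e at 4.16, and an adjusted p = 0.674 with an estimated correlation. Without pulmonary replicate 4 their median was 0.17 and the call ended, with Jchain at 2.82, Mzb1 at 1.68 and Cd3e at 0.42. Cell cycle genes had 17 of 17 higher (median 3.14, adjusted p = 0.0024, 0 adjusted over the list alone), with Tpx2 at 2.66, Aurkb at 6.12 and Rrm2 at 3.91, and an adjusted p = 0.731 with an estimated correlation. Pulmonary replicate 4 was the highest library for 17 of 18 of them, and without it the median turned to −0.69 and the call ended, with Tpx2 at 0.65, Aurkb at −0.94 and Rrm2 at 0.22.

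The list of gut and pancreas markers had 5 tested genes (median 0.69, adjusted p = 0.0024, adjusted p = 0.374 with an estimated correlation, 2 adjusted over the list alone). The members that moved were Reg3b and Reg3g, secreted antimicrobial lectins, with 0 mesenteric counts and 136 and 504 pulmonary counts, at least 40.8-fold and at least 151-fold higher. Reg3g varied widely between the pulmonary libraries (13.5 ± 17.6 CPM, SD, n = 3). Its fitted log2 fold change of 10.46 ran from 8.50 to 10.92 with 1 library left out. Vil1, a protein of the intestinal brush border, was at 0.69 (0.058 without pulmonary replicate 2). The call ended without mesenteric replicate 1 (0.12) or pulmonary replicate 2 (0.22), and the median was 1.41, 1.40 and 1.56 without mesenteric replicate 2, mesenteric replicate 3 and pulmonary replicate 1. Cartilage markers (median 1.04, adjusted p = 0.0360, 0 adjusted over the list alone) had Chad at 3.31 (1.78 without pulmonary replicate 2), Col9a2 at 2.07 (1.16 without pulmonary replicate 4) and Col11a1 at −4.12, and pulmonary replicate 2 was the highest library for 11 of 15 of them. That call ended without mesenteric replicate 2 (1.89) or pulmonary replicate 2 (0.39), and the median was 1.97 and 1.74 without mesenteric replicates 1 and 3. The list had an adjusted p = 0.674 with an estimated correlation.

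Macrophage markers (median 0.62, adjusted p = 0.0335), mast cell and granulocyte markers (0.56, adjusted p = 0.0344) and mitochondrially encoded genes (0.44, adjusted p = 0.0421) were higher, each with 0 adjusted over the list alone. With an estimated correlation their adjusted p = 0.674, 0.674 and 0.760. Csf1r, a macrophage growth factor receptor, was at 0.66, Lyz2 at 1.78 and C1qa at 0.99 (0.31 and 0.36 without pulmonary replicate 4), and that call ended without mesenteric replicate 1 (0.36) or 3 (0.37) or pulmonary replicate 4 (0.31), with a median of 1.05 without mesenteric replicate 2. Mmp8 was at 2.93, Hdc at 1.17 and Mcpt1l1 at 1.11 (0.55 without pulmonary replicate 1), and that call ended without mesenteric replicate 1 (0.33) or 3 (0.48) or pulmonary replicate 1 (0.12) or 4 (0.58), with a median of 1.20 without mesenteric replicate 2. Mt-co1 was at 0.70, Mt-atp8 at 0.69 (0.42 and 0.28 without pulmonary replicate 4) and Mt-nd6 at 0.45, and that call ended without mesenteric replicate 1 (0.31) or 2 (0.46) or pulmonary replicate 2 (0.35) or 4 (0.16). With pulmonary replicate 1 as the only pulmonary library, the median of the mitochondrially encoded list turned to −0.20 and Mt-co1 to −0.25.

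The remaining lists did not pass. Brown fat markers had an adjusted p of 0.0508, Wnt signalling 0.0590, Notch signalling 0.156, heat shock proteins 0.175, lipid metabolism 0.203, the respiratory chain 0.218, interferon response 0.323, adipocyte markers 0.331 with Adipoq at −0.69 (−1.28 and −0.12 without pulmonary replicates 1 and 4), and sugar uptake and glycolysis 0.463. Thoracic transcription factors had 0.517, the clock 0.519, insulin signalling 0.531, hypoxia response and redox genes 0.532 each, and pericytes 0.661. Potassium channels had 0.864, skeletal muscle markers, the unfolded protein response and ribosomal proteins 0.883 each, and epigenetic enzymes and calcium handling 0.971 each. Lung epithelium and red cell lists had too few tested genes.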

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

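The newer quasi-likelihood method, the contractile score as a covariate and pulmonary replicate 1 as the only pulmonary library were tests chosen after the results were seen. All other alternatives were planned. The alternatives moved the median log2 fold change over genes by at most 0.0143 for a change of scaling. In the high-sucrose comparison, edgeR called 0 genes under every setting, with 132 to 812 genes at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 3. The self-test recovered 64.5% of genes changed 4-fold and 8.33% of genes changed 2-fold there. It changed 200 genes per draw, and the simulated genes varied independently. Recovery depends on how many genes change, so it gives no bound on what a count of 0 excludes where fewer do. In the artery comparison, where the self-test recovered 10.9% and 0.314%, edgeR called 2 genes with median-ratio size factors, without a filter and with a stricter filter. With upper quartile factors it called 3.

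With the replicate number as a block, edgeR called 0 genes in the high-sucrose comparison and 36 in the artery comparison (2 before), both earlier genes among them, and 13 and 18 lists. These kept 10 of the 10 earlier lists in the first comparison and 10 of the 22 in the second, where mesenteric replicate 3 and pulmonary replicate 4 have no partner and the blocked contrast rests on 2 pairs. Over all genes, the differences of samples with the same number did not go together, so the numbers are not taken as pairs. The correlations were 0.21, −0.29 and 0.13 across 13995 genes in the first comparison, and 0.17 and −0.17 across 14315 in the second. They cannot exclude a link in some genes. The immediate early list had means of 8.63 and 8.72 log2 CPM in the control and high-sucrose mesenteric replicates numbered 3. In the other mesenteric libraries its mean was 6.75 to 7.37 log2 CPM. The heat shock list, at 7.73 and 9.39 log2 CPM in the replicates numbered 3, did not go with the number. Blocking turned the artery values of Aurkb to −0.57, Cd3e to −0.12, the cell cycle list to −0.23 and the glucocorticoid list to 0.14. The cause was not tested.

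The artery comparison gave 462 genes with DESeq2, 33 with limma-voom, which gave pulmonary replicate 4 a weight of 0.19, 38 with all 9 libraries in the fit, 9 with the newer method, 20 with the contractile score as covariate and 0 with pulmonary replicate 1 alone, which was assumed to vary like the mesenteric libraries. Leaving out 1 library gave from 0 to 22 genes, the latter without pulmonary replicate 4, and from 11 to 23 lists. The 0 counts came with 741 to 1879 genes at an unadjusted p under 0.05. Lists numbered 14 with the covariate, 13 with pulmonary replicate 1 alone, and 0 with an estimated correlation and with fry, as also in the high-sucrose comparison. Fewer samples or another estimate of the spread enter these fits, and which of them moved the counts was not tested.

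Of 719 values of 45 named genes in the high-sucrose comparison, 705 kept direction and side of the threshold, 3 passed with DESeq2 and 11 reversed. Of 1316 values of 78 genes in the artery comparison, 1197 kept both, 92 newly passed, 12 no longer passed and 15 reversed. Of list values, 87 of 120 and 164 of 286 kept both, 32 and 116 no longer passed, and 1 and 6 reversed. The cause of the reversals was not tested. Some genes had no value: Cd3g, Aurkb and Vil1 with the stricter filter, Mmp8 without pulmonary replicate 4, Mzb1 with pulmonary replicate 1 alone, and Aurkb, Cd3e, Cxcl13, Jchain, Mzb1 and Rrm2 with DESeq2, which gave them no adjusted p. Other pseudocounts and filters on normalised values were not run, because the files hold counts.

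In the high-sucrose comparison, Adipoq turned to −0.14 with limma-voom. Leaving out 1 library, values ran from −0.12 to 0.41 for Adipoq (−0.03 without control replicate 1, −0.05 without high-sucrose replicate 3), −0.98 to 0.26 for Acta2, −0.74 to 0.26 for Myh11, −0.27 to 0.20 for Pecam1 (0.05 and 0.04 without high-sucrose replicates 1 and 2), −1.10 to 0.060 for Cd79a, −0.080 to 0.85 for Dnajb9 and −0.21 to 0.83 for the cell cycle list.

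In the artery comparison, Aurkb turned to −0.0059 with limma-voom, −0.78 with the covariate and −0.48 with pulmonary replicate 1 alone. The covariate also turned Rrm2 to −0.064 and the cell cycle list to −0.91. With pulmonary replicate 1 alone, Mt-co1 was at −0.25, Vil1 at −0.53, Myh6 at −0.63, Adipoq at 0.055, the cell cycle list at −0.42 and the mitochondrially encoded list at −0.20. Leaving out 1 library, values ran from −0.94 to 6.69 for Aurkb, −0.45 to 0.78 for Acta2 (−0.02 without mesenteric replicate 3, −0.24 and −0.41 without pulmonary replicates 1 and 2) and −0.69 to 3.69 for the cell cycle list.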

Other observations

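The test of a sample swap and the count of splits for the genes of the high-sucrose comparison were tests chosen after the result was seen, and the genes of the next paragraphs were chosen after their values were seen.

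Transcription factors of lung mesenchyme and the cardiac outflow tract did not pass as a list between arteries (adjusted p = 0.517, median −0.16), but 5 members were higher and 2 lower in pulmonary artery when adjusted over the list alone. Tbx5 and Gata4, which pattern heart and lung, had 0 mesenteric counts and 777 and 667 pulmonary counts, at least 233-fold and at least 200-fold higher with the floor of 3 counts over the group. Both were highest in pulmonary replicate 2, the library with the highest cardiac transcripts (47.0 and 40.3 CPM), and were at 6.84 and 4.92 CPM in replicate 1, where Myh6 was at 2.65 CPM. Gata5 had 1 and 106 counts (mesenteric over pulmonary ratio 0.0105, counting interval 0.000263 to 0.0597). Tbx4, of lung mesenchyme, was at 0.11 ± 0.02 and 4.85 ± 5.82 CPM (SD, n = 3). Tcf21 was at 91.1 ± 76.8 CPM in mesenteric and 12.1 ± 3.02 CPM in pulmonary artery, and Meox2 at 37.2 ± 5.35 and 14.7 ± 4.82 CPM.

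Single members of lists without a call also differed between arteries when adjusted over the list alone. Cacna1d, a pore subunit of L-type calcium channels, was at 1.02 ± 0.50 CPM in mesenteric and 40.5 ± 24.3 CPM in pulmonary artery (log2 fold change 5.28, adjusted p over all genes 0.123), while Cacna1c, the main L-type subunit of arterial muscle, was at 103 ± 19.3 and 105 ± 68.6 CPM. Kcne4, a modulator of potassium channels, was at 37.6 ± 8.81 and 9.11 ± 1.69 CPM, and Slc2a3, a glucose transporter, at 90.8 ± 15.5 and 20.8 ± 10.8 CPM. Cacna1d and Slc2a3 were among the 22 genes that passed without pulmonary replicate 4, with log2 fold changes of 5.68 and −2.61.

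Within the mesenteric artery, Hoxa9 was at 18.8 and 15.1 CPM in control replicates 1 and 2 and 0 CPM in replicate 3, and at 17.9, 15.2 and 1.34 CPM in high-sucrose replicates 1, 2 and 3. Fos, an immediate early gene, was at 2557 and 2270 CPM in the 2 replicates numbered 3 and between 217 and 705 CPM in the other 4 mesenteric libraries. Hba-a2, a haemoglobin chain, was at 411, 190 and 3626 CPM in high-sucrose replicates 1, 2 and 3 and between 2116 and 2732 CPM in the controls. Spon2 was at 20.4, 22.0 and 54.1 CPM in high-sucrose replicates 1, 2 and 3 and between 64.9 and 102 CPM in the controls, and did not pass there.

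Transcripts of other tissues were present in all 3 pulmonary libraries, and those of replicates 2 and 4 were tested. Second lists of marker genes that share 0 genes with the first were written before they were looked up. In pulmonary replicate 4, 13 of 14 B cell genes (92.9%) and 15 of 16 airway genes (93.8%) were at their highest of the 9 libraries, with Coro1a at 756 CPM, Pou2af1 at 307 CPM, Muc5b at 486 CPM and Bpifb1 at 421 CPM, and in pulmonary replicate 2, 10 of 11 cardiac genes (90.9%), with Csrp3 at 903 CPM and Ldb3 at 880 CPM. Of these lists, 5, 2 and 5 genes were at 1 CPM or more in every mesenteric control, and no sort that would remove such cells is named in the labels. A swap of replicate 4 with an undiluted mesenteric library is argued against, since 2 of 18 Hox genes (11.1%) lay within or above the mesenteric range in it. Hoxa9 counted as within at 0 CPM, because mesenteric control replicate 3 was also at 0 CPM. The count cannot settle a swap with a diluted mesenteric library. Hoxb3 and Hoxb4, which did not pass between arteries, also lay below the range (8.58 and 6.91 CPM). Hoxc8 had 0 counts in replicate 4 and at least 106 in each mesenteric library. Replicates 2 and 4 had been picked by the first lists, so the second lists were likely to pass. The second lists repeat the pattern with other genes and cannot tell which tissue the transcripts came from. A candidate explanation, not told apart from other sources of such cells, is lymph node and airway tissue in replicate 4 and cardiac muscle in replicate 2. Cardiac transcripts in replicate 4 (Csrp3 at 49.6 CPM) and Ucp1 and Msln in replicate 1 (12.6 and 50.7 CPM) were not tested for a source. No biological explanation was tested.

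The heat shock and clock lists were higher in the high-sucrose group by their medians, although the mean of the heat shock list in high-sucrose replicate 2 lay below the controls and that of the clock list overlapped them in replicates 2 and 3. With the contractile score as covariate, 97.5% of the heat shock median was left (0.73 against 0.75). The limit of 80% set before was wrong as a test, because the scores differed between the groups by only 0.036 ± 0.53 (SE), with 10.4 ± 0.39 in the high-sucrose and 10.3 ± 0.83 in the control group (SD, n = 3), so the covariate could hardly move the median whatever the cause. A different content of smooth muscle stays open. Another time of day at collection may account for the clock genes and stays open. The mean of 10 genes of the Per and Dbp limb of the clock minus that of 5 genes of the Arntl limb was higher by 1.46 ± 1.03 (SE) on the log2 scale (exact permutation test, 2-sided, p = 0.3, where 0.1 is the smallest possible), with 0.65, 1.53 and −1.76 in high-sucrose replicates 1, 2 and 3 and −1.43, −1.78 and −0.77 in the controls. The diet of the dams stays among the open explanations, untested.

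The 6 libraries of a comparison make 10 splits into equal groups, too few for a share under 0.05. In the high-sucrose comparison 10 of 10 splits gave at least the real count of 0 genes by edgeR (highest other 0). No split can give fewer than 0, so this count could not come out otherwise and decides nothing. By edgeR there were 279 genes at an unadjusted p under 0.05 in the real split and from 141 to 1676 in the others. DESeq2, which called 3 genes in the real split, was not run on the others. Of the splits, 6 of 10 gave at least 10 lists (highest other 16). In the artery comparison 1 of 10 gave at least 2 genes (highest other 1) and 3 of 10 gave at least 22 lists (highest other 27). The split with 1676 genes set control replicate 1 and high-sucrose replicates 1 and 2 against the other 3 libraries.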
